A study of Danio rerio with 3 samples.

How the data were processed

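The data came from 3 samples of whole zebrafish embryos measured on two-channel oligonucleotide arrays. Per the labels' protocols, embryos were exposed from 24 hpf (hours post fertilization) for 24 h to Aroclor 1254 at 71.9 mg/L and collected at 48 hpf. Control embryos stayed in medium at 28.5 °C. Aroclor 1254 is a commercial mixture of polychlorinated biphenyls. From each of the exposed and control samples, 2 µg of total RNA was amplified and labelled with Cy3 and Cy5. Each of the 3 samples is labelled a biological replicate and sets exposed against control embryos, so all belong to 1 group and the contrast lies inside each value. The labels do not say from which cultures or clutches the replicates came, so p-values measure the spread between these 3 samples.

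The authors deposited 1 table with a number per row and 1 log ratio per sample, and these values were used as deposited. The unit was taken as a log2 ratio. The deposited log2 values are signed, centred near 0 and reach -12.9, which as log10 would lie outside any scanner's range. The natural logarithm could not be excluded, and all folds printed here assume log2. Background correction, normalization, the rule that left rows without a value, and the scanner are not given in the sources used here. A dye swap is part of the design, but how swapped hybridizations were combined, and which condition is the numerator, is not given. Both channels carry both dyes in the labels. Signs are therefore reported as deposited: "positive" and "negative" describe the value in the table, and no direction of exposure is stated. The labels list control embryos as the first channel and exposed embryos as the second, which is the only hint they hold. Array signal levels were not used here, so the number of samples limits the precision.

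Rows were named through the platform's probe table, which gives 1 gene symbol to 21060 of the 45219 rows, none to 24159 and several to none. Gene IDs of 20132 of these probes were found in the RefSeq gene table of the GRCz12tu assembly, and no symbol needed updating. With the row numbers taken as given, probes of 1 gene did not go together. Over 8078 pairs of probes of 1 gene, the correlation of having a value was 0.0085, and over 420 pairs measured in all samples the Pearson r of the mean log2 ratio was 0.029. Other numberings were then searched for. Reversing the numbers and transposing or flipping them over the smaller divisors of 45220 (166 numberings) gave at most 0.03 and 0.161. Shifts of up to 3000 rows either way (6000 numberings) gave at most 0.042 and 0.219. The values had a repeat of 266 rows in each sample, which points to a grid of 266 by 170 spots. On that grid 320 distinct ways of counting were compared (1600 combinations of counting by row or by column, from each corner, with staggered rows or not). In 1 of them the table counts spots along staggered rows of 85 and the deposited rows count down columns of 266 from the opposite corner. That numbering gave a correlation of having a value of 0.384 over the 8078 pairs and r = 0.754 over 2001 pairs (0.749 without cyp1a). Only 152 of these pairs have different accessions, and these gave r = 0.514. The highest values among the other numberings on the grid were 0.029 and 0.12, and among 100 shuffles 0.031 and 0.104. All gene names below rest on this renumbering. It is an inference from these data, made after the values were seen. The numberings were ranked by the correlation of having a value, and the likeness of the exposed-against-control ratios of probes of 1 gene was looked at too, so the choice is not independent of those ratios. Counts of rows do not depend on it, except where only rows with a gene were kept. The probe table used here has no column that marks control spots, so the planned removal of control spots was not done, and rows unnamed here stayed in the counts of rows.

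Rows with a value in all 3 samples (10200) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, against 0, 2-sided). Gene values are the mean over a gene's measured rows in each sample (5897 genes, 1414 with several rows), fitted the same way. The Benjamini-Hochberg threshold was an adjusted p of 0.05. The fit has 2 residual degrees of freedom and gained 4.6 from the prior. Of the 37 gene lists written before the data were examined, 32 held at least 5 genes and were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. The tests, the lists, the naming rule and the settings listed first below were all fixed before the data were examined.

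Named genes are cyp1a and every measured AhR (aryl hydrocarbon receptor) target of the list. To these were added, among genes with 1 sign in all 3 samples, up to 12 passing genes in each direction by size, or, where fewer passed, the passing genes and then the largest moderated statistics up to 8. The 4 members with the smallest p of each list that passed camera complete the set. Clone and locus identifiers were counted but not named. Genes named outside the rule are marked as chosen after their values were seen.

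The fits were tested on simulated data with 5897 genes, 200 of them changed. For changes of 1 on the log2 scale 8 of 50 were recovered, for 2 it was 45 of 50, and for 3 and 4 it was 49 of 50 each, with 7 false calls among 158. A shift of 0.5 on the log2 scale in 1 of the 32 lists was called by camera, with 0 other lists. The simulated genes were drawn independently of each other and with equal variance in the 3 samples. In the data, the ribosomal, erythroid and proteasome lists had estimated correlations of 0.67, 0.68 and 0.71. The simulation therefore cannot show how often camera calls correlated lists in error. Its recovery counts hold for samples of equal spread and for 200 changed genes, since the Benjamini-Hochberg cutoff depends on how many genes pass. In the data 1 gene passed, and acot14, at -2.07 on the log2 scale, missed the threshold (adjusted p = 0.0721, limma). The other settings tried were median centring, scaling to equal median absolute value, quantile normalization, robust and ordinary statistics, array weights, rows measured in at least 2 samples, a filter on ratios under 0.1, limma's treat against 1.2-fold, the median of a gene's probes, genes with a single probe, turned signs and each replicate left out. Scaling was planned with limma's normalizeBetweenArrays, which gave no values on signed ratios, and normalizeMedianAbsValues was used in its place. Settings chosen after seeing the data were removal of a position trend over the grid (loess, span 0.1), the row numbers as given, only rows with a gene, and Spearman correlation. Also chosen then were the scaled and quantile-normalized values for the gene lists, and the quantile-normalized and gene values for the correlations between samples.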

Results

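Gene expression was compared between whole zebrafish embryos exposed to Aroclor 1254 and control embryos at 48 hpf, in 3 replicates. The table held 45219 rows. A value was present for 12735 rows in replicate 1, 10487 in replicate 2 and 12062 in replicate 3, and 10200 rows had one in all 3. The standard deviation of the log2 ratios over these common rows was 0.82, 0.97 and 0.62 in replicates 1, 2 and 3, with medians of 0.01, -0.02 and -0.04. Across rows, which are not independent replicates, the Pearson correlation was 0.302 between replicates 1 and 2, 0.49 between 1 and 3, and 0.332 between 2 and 3. Signs are those of the deposited ratios throughout, since the condition in the numerator is not stated. Gene names rest on a renumbering of the rows that was inferred from the values.

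Once the rows were paired with genes, the gene lists differed widely in how many probes had a value. Proteasome genes had one for 89.4% of 47 probes and ribosomal protein genes for 85.2% of 108. Next were proliferation genes with 83% of 53, hypoxia and glycolysis genes with 78.5% of 65, unfolded protein response genes with 75% of 44, skeletal muscle genes with 74.3% of 74 and neural genes with 72.6% of 84. Few probes had a value for photoreceptor genes (16.2% of 74), exocrine pancreas genes (8.7% of 23), and cytochrome P450 enzymes and transporters outside the cyp1 family (18.2% of 33). None of the 17 probes of the estrogen response list (10 genes on the array) had one. Of all probes with a gene, 45.4% had a value. With the row numbers as given, the same lists lay between 17.1% and 38.3%, around the 28.7% of all gene-paired rows.

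**Figure D1:**
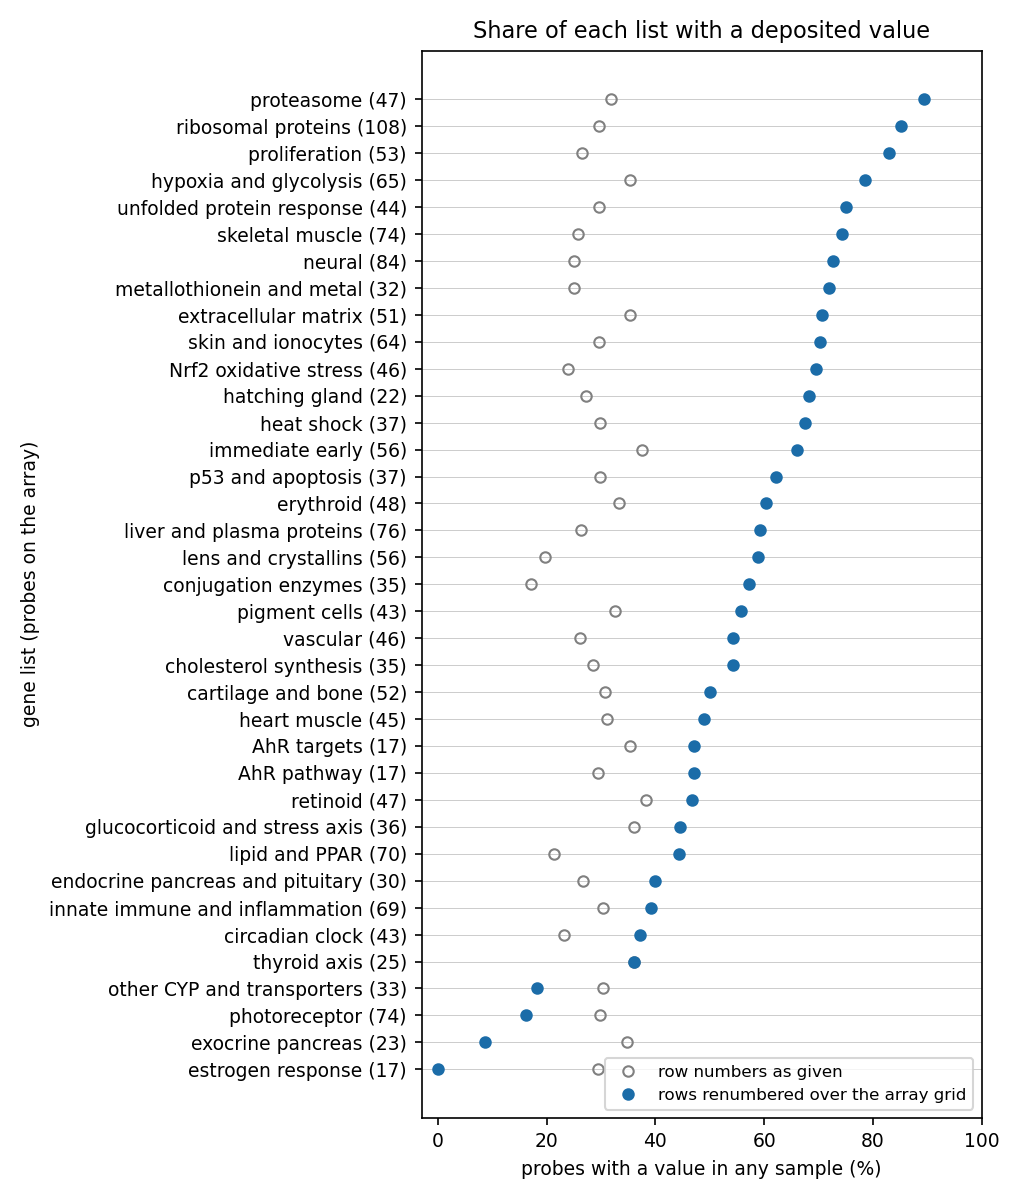
Percent of each gene list's probes with a deposited value in any sample (x axis), for 37 lists with their number of probes in parentheses (y axis), under the renumbered rows (filled) and the row numbers as given (open). Renumbered shares run from 0% for the estrogen response list to 89.4% for the proteasome, while the open points stay between 17.1% and 38.3%.

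The first question was whether exposure changed the targets of the aryl hydrocarbon receptor, the ligand-activated transcription factor that binds dioxin-like biphenyls. The gene cyp1a, a cytochrome P450 monooxygenase and the standard marker of this receptor, had the largest ratio of all genes, 7.90 ± 0.78 on the log2 scale (SD, n = 3; 239-fold), with an adjusted p of 0.000812 in limma. It was positive in each replicate, at 7.07, 8.61 and 8.02. Its measured rows differed in size: 1 gave 10.48 ± 1.28 and the other 5.32 ± 0.57 (SD, n = 3), and the third cyp1a probe had no value. For sult6b1, a sulfotransferase, the ratio was 1.45 ± 0.48 (SD, n = 3; 2.73-fold, adjusted p = 0.152, limma), positive in 3 of 3 samples. For tiparp, a mono-ADP-ribosyltransferase, it was 0.16 ± 0.35 (SD, n = 3; adjusted p = 0.769, limma).

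Other members of this list were measured in part. The gene cyp1c1 had a value for 1 of its 3 probes, in replicates 1 and 3, at 3.2 and 4.45. In the fit of genes measured in at least 2 samples its mean of 3.82 had an adjusted p of 0.0648 in limma. A cyp1b1 probe stood at 0.55 and -0.08 in the same replicates. The 2 foxq1b probes with a value read 0.80 and 2.5 in replicate 1 and -1.16 and -0.46 in replicate 3. No probe of the receptor repressors ahrra and ahrrb, or of wfikkn1, had a value. The receptor gene ahr2 itself had a ratio of -0.06 ± 0.21 (SD, n = 3; adjusted p = 0.921, limma). It was chosen after its value was seen.

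The second question was which genes differed across the array. At an adjusted p of 0.05 in limma, 7 of 10200 rows passed, 4 positive and 3 negative, and 1 of 5897 genes passed, cyp1a. At an unadjusted p of 0.05, 1923 rows and 954 genes did. The rows that passed were both cyp1a rows, 1 row of g6pc1a.1 (2.76 ± 0.36), 1 row of dedd1 (2.66 ± 0.41; SD, n = 3 each), named after its value was seen, and 3 rows without a gene name in the probe table, at -3.54, -4.93 and -5.15. As a gene, with its measured rows averaged, dedd1 was not among the 8 positive genes named by the rule. A ratio of at least 1.5-fold in the same direction in all 3 samples was found for 314 genes, 152 positive and 162 negative, and of at least 2-fold for 78, 45 positive and 33 negative. When the sign of a single replicate was turned, 25 to 58 genes reached 1.5-fold. Counts by adjusted p moved with the scaling: quantile normalization gave 52 rows (24 positive, 28 negative) and 61 genes (38 positive, 23 negative), and scaling 53 rows (24 positive, 29 negative) and 45 genes (28 positive, 17 negative). Without replicate 2, 48 rows passed, without replicate 3, 22 genes did, and the ordinary statistic called 0 of either (1104 rows and 600 genes at an unadjusted p of 0.05). The same sign in all 3 samples was seen in 43% of genes, where chance gives 25%. Of the 1414 genes with several rows, 350 had rows of opposite mean sign, and of the 553 with at least 1 row at 1.5-fold, 70 did.

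Among positive genes after cyp1a, the largest moderated statistic was that of g6pc1a.1, a catalytic subunit of glucose-6-phosphatase, which releases glucose at the end of gluconeogenesis (2.76 ± 0.36, 6.76-fold, adjusted p = 0.0614). Next were the adenylate cyclase adcy2b (2.21 ± 0.24), the small heat shock protein gene hspb9l (2.08 ± 0.12, from 5 rows), the collagenase mmp13a (2.18 ± 0.41), mibp2 (1.90 ± 0.18), the syntaxin gene stx11b.1 (1.88 ± 0.32) and tcima (1.77 ± 0.24). Their adjusted p in limma ran from 0.0721 to 0.0996, so none passed.

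The negative genes with the largest moderated statistics were the acyl-CoA thioesterase acot14 (-2.07 ± 0.05), the splicing factor srsf4 (-2.23 ± 0.34), the transcription factor klf11a (-1.94 ± 0.27) and rgs2, a regulator of G protein signalling (-2.44 ± 0.69). They were followed by apobb.1, an apolipoprotein B of yolk and plasma lipoproteins (-1.65 ± 0.16), the co-chaperone dnajc21 (-1.92 ± 0.52), rsrp1 (-1.51 ± 0.11) and fkbp5, a co-chaperone of the glucocorticoid receptor (-3.82 ± 1.64; replicates at -5.69, -3.10 and -2.66). All values are SD with n = 3. The adjusted p of these genes in limma lay between 0.0721 and 0.112. After quantile normalization 61 genes passed, and each of the 15 genes named in these 2 paragraphs was among them. They were chosen for large statistics in the same samples, so this adds no independent support.

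**Figure D2:**
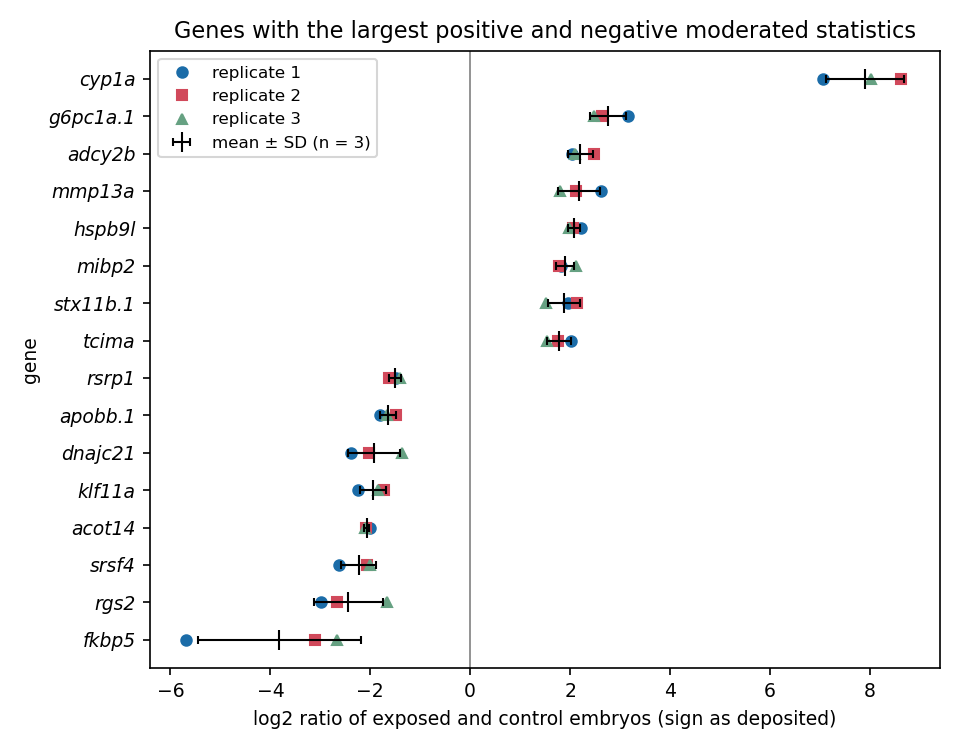
Log2 ratios (x axis, sign as deposited) of the 8 positive and 8 negative genes with the largest moderated statistics (y axis) in each replicate (coloured symbols), with mean ± SD (black, n = 3). The replicates of cyp1a lie between 7.07 and 8.61, and those of fkbp5 between -5.69 and -2.66.

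The third question was whether groups of genes moved together. With camera at its preset correlation, 6 of 32 lists passed. With an estimated correlation none did (lowest adjusted p = 0.826, and lists at unadjusted p under 0.05 were also 0), and fry called none (lowest adjusted p = 0.54, 2 lists at unadjusted p under 0.05). The preset test also called 6 to 9 lists when the sign of 1 replicate was turned. Over all genes, 43% had 1 sign in all 3 samples, and 954 of 5897 had an unadjusted limma p under 0.05. The share with 1 sign was lower in the ribosomal, erythroid and immediate early lists, similar in the proteasome list and higher in the other lists that passed. The share at that p was lower in the ribosomal, proteasome and erythroid lists and higher in the others.

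Genes of the unfolded protein response were negative as a group (median -0.75, adjusted p = 0.00745 with camera, 0.826 with an estimated correlation). Of its 21 measured genes, 13 were negative and 1 was positive in all 3 samples. None passed over all genes (10 were at an unadjusted limma p under 0.05), and 8 did when adjusted over the list alone, all of them negative. They included the endoplasmic reticulum chaperone hspa5, also known as BiP (-1.35 ± 0.51), the secreted factor manf (-2.04 ± 0.77), and the chaperone partners dnajc3a (-1.36 ± 0.68) and dnajb11 (-1.48 ± 0.98; SD, n = 3 each). The list median was -0.66, -0.80 and -0.19 in replicates 1, 2 and 3. In camera at its preset correlation, it was the only one of the 6 lists that stayed past the threshold whichever replicate was left out. That test also called 6 to 9 lists when the sign of 1 replicate was turned, so this does not set the list apart from error. The list median was -0.66 without replicate 1, -0.48 without replicate 2 and -0.98 without replicate 3.

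Ribosomal protein genes were positive as a group (median 0.29, adjusted p = 7.41e-05 with camera, 0.826 with an estimated correlation). Of 66 genes, 18 were positive and 0 negative in all samples, and none passed over all genes or adjusted over the list alone (9 at an unadjusted limma p under 0.05). Examples were rpl18 (0.96 ± 0.06), rps10 (1.16 ± 0.60), rpl7 (0.95 ± 0.31) and rpl29 (0.86 ± 0.37). Proteasome genes were negative (median -0.46, adjusted p = 0.0159, and 0.826 with an estimated correlation). Of 33 genes, 13 were negative and 1 positive in all samples, and none passed in either way (3 at an unadjusted limma p under 0.05). Examples were psme3 (-0.86 ± 0.60), psmc4 (-0.65 ± 0.17), psmd6 (-0.65 ± 0.42) and psmd1 (-0.72 ± 0.69). Both shifts rested on replicate 2: the ribosomal median was 0.08, 0.95 and -0.12 and the proteasome median -0.10, -1.04 and -0.03 in replicates 1, 2 and 3. Without replicate 2 the medians were -0.04 and -0.11, with adjusted p of 0.771 and 0.947 in camera.

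Erythroid genes were positive (median 0.47, adjusted p = 0.0229, and 0.826 with an estimated correlation), and again rested on replicate 2, whose median was 1.13 against 0.16 and -0.26 in replicates 1 and 3. Without replicate 2 the median was -0.003 (adjusted p = 0.947). Of 20 genes, 6 were positive and 0 negative in all samples, and none passed over all genes or adjusted over the list alone (3 at an unadjusted limma p under 0.05). The call was also lost after scaling (median 0.39, adjusted p = 0.0588 in camera) and quantile normalization (median 0.42, adjusted p = 0.055 in camera), with medians not far from the 0.47 of the main fit. The cytoskeletal ankyrin ank1a stood at 1.05 ± 0.07, the heme synthesis enzyme hmbsb at 1.49 ± 1.01, znfl2a at 1.40 ± 1.3 and the embryonic beta globin hbbe3 at 1.23 ± 1.55, from 1.76, 2.45 and -0.51. Some embryonic globin genes are near-identical copies, so their probes can share signal.

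Vascular genes were positive (median 0.46, adjusted p = 0.0159, and 0.826 with an estimated correlation), with 10 of 16 positive and 1 negative in all samples. The vascular median was 0.48, 0.69 and 0.11 in replicates 1, 2 and 3, and 0.28 without replicate 2. The 4 with the smallest limma p were aqp8a.1 (0.88 ± 0.50), the endothelial factor egfl7 (0.73 ± 0.25), aqp1a.1 (0.77 ± 0.69) and the tight junction gene cldn5b (0.68 ± 0.61). The mean of aqp1a.1 fell to 0.38 without replicate 2, and that of cldn5b to 0.33 without replicate 1. With 1 replicate left out, the lowest means of aqp8a.1 and egfl7 were 0.63 and 0.64. Immediate early genes were also positive (median 0.15, adjusted p = 0.0466, and 0.826 with an estimated correlation), with 7 of 21 positive and 0 negative in all samples. The phosphatase dusp5 (1.25 ± 0.23) passed adjusted over the list alone, and fosab (2.02 ± 1.34), myca (0.78 ± 0.39) and btg2 (0.76 ± 0.41) did not. No gene of either list passed over all genes (3 vascular and 4 immediate early genes at an unadjusted limma p under 0.05). Without replicate 2 both lists had an adjusted p of 0.0831, and the immediate early list also missed the threshold without replicate 1 (0.103), without replicate 3 (0.0683), after scaling (0.0588) and after quantile normalization (0.055). Its median was 0.12, 0.19 and 0.29 without replicates 1, 2 and 3, 0.17 after scaling and 0.17 after quantile normalization.

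The other 26 tested lists did not pass. The AhR target, AhR pathway, thyroid axis, estrogen response and exocrine pancreas lists held too few measured genes and were not tested. The Nrf2 oxidative stress list had a median of -0.32 over 18 genes (adjusted p = 0.615), with a mean of -0.11. The heat shock list had a median of -0.32 over 16 genes (adjusted p = 0.151), and hypoxia and glycolysis genes one of 0.20 over 29 genes (adjusted p = 0.05005, all camera). Some single genes passed adjusted over their list alone, without adjustment across lists, and are named after their values were seen. None of them passed over all genes, and further lists held such genes too. The glucocorticoid and stress axis list had 9 measured genes. In it these were fkbp5, g6pc1a.1, the insulin-like growth factor binding protein igfbp1a (1.78 ± 0.91) and the kinase sgk1 (0.91 ± 0.25). Over all genes their adjusted p in limma ran from 0.0614 for g6pc1a.1 to 0.194 for sgk1. Among 5 measured cytochrome P450 enzymes and transporters they were abcg2a (0.88 ± 0.42), cyp3c1 (0.85 ± 0.33) and cyp2y3 (-0.68 ± 0.15). Over all genes these 3 had an adjusted p of 0.214, 0.214 and 0.247 in limma.

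**Figure D3:**
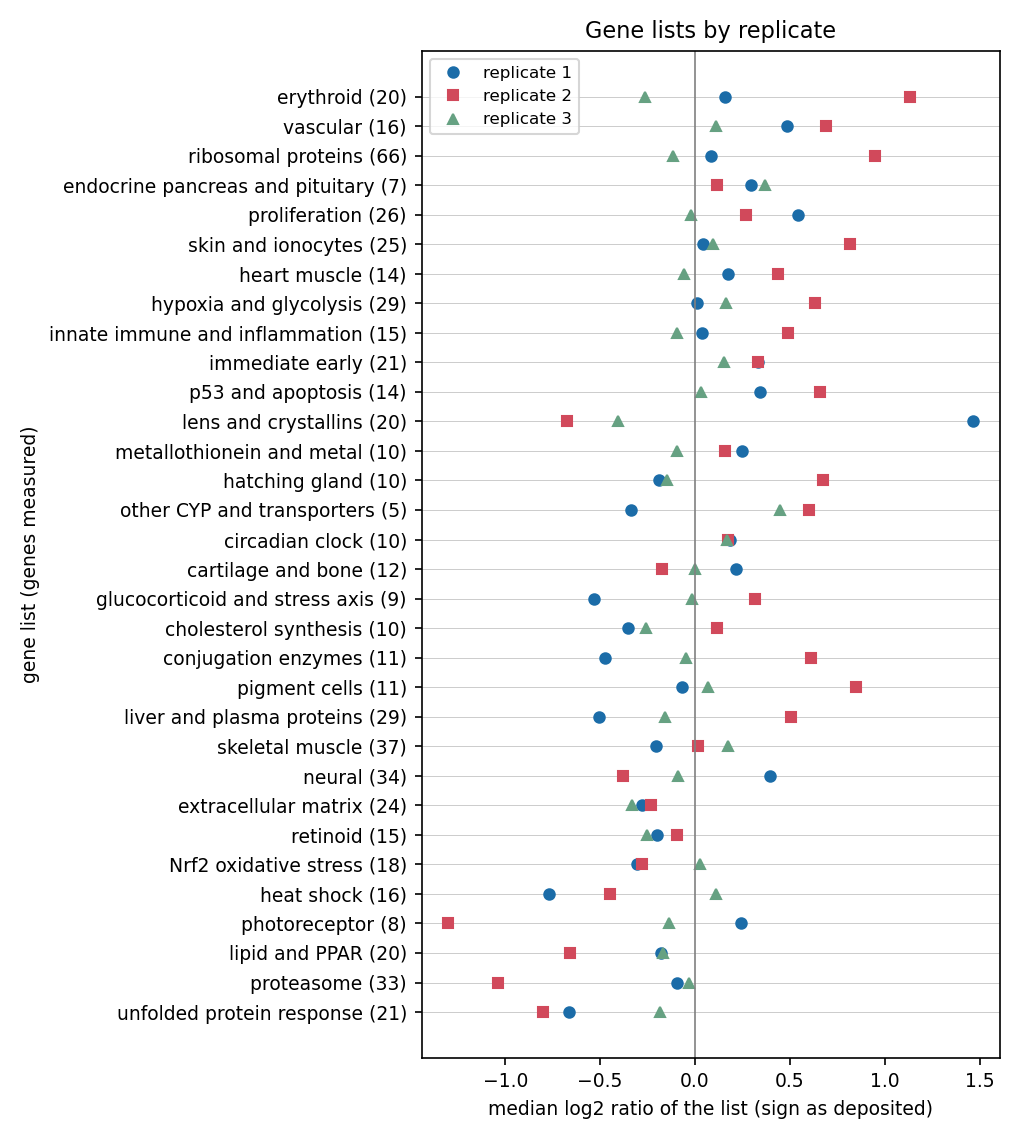
Median log2 ratio (x axis, sign as deposited) of each of 32 gene lists (y axis, genes measured in parentheses) in each replicate (coloured symbols). Replicate 2 stands apart from the others for ribosomal protein genes (0.95) and proteasome genes (-1.04), and replicate 1 for lens and crystallin genes (1.47).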

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

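The direction of all 42 named genes held under median centring, quantile normalization, removal of the position trend and each replicate left out. All but tiparp and hbbe3 had 1 sign in all 3 samples, so leaving out a replicate could not turn them. Only cyp1a passed in the main fit, so for the others staying on the same side of the threshold meant not passing. Of the 252 values in these settings, 231 stayed on the same side. The other 21 newly passed, 16 of them under quantile normalization. Equal scaling gave 53 rows and 45 genes, quantile normalization 52 rows and 61 genes (44 genes called by both), and array weights, which gave replicates 1, 2 and 3 weights of 0.97, 0.47 and 2.18, gave 107 rows and 42 genes. The ordinary statistic called 0 rows and 0 genes (1104 and 600 at an unadjusted p of 0.05), and genes with a single probe, which leave out cyp1a by construction, gave 0 (700 at an unadjusted p of 0.05). Rows measured in at least 2 samples gave 62 rows, and only rows with a gene gave 3, against 4 such rows among the 7. Median centring and the filter on small ratios gave 2 genes each. The row numbers as given gave 8 genes, 252 genes of 1.5-fold and 0 lists. Leaving out 1 replicate gave 9 to 48 rows (48 without replicate 2) and 1 to 22 genes (22 without replicate 3, 12 of them also called after scaling). It gave 523 to 909 genes of 1.5-fold, where fewer samples had to pass, and 2-fold gave 78. With fry and with an estimated correlation 0 lists passed, and leaving out 1 replicate gave 1 to 8 lists (1 without replicate 2), and scaling and quantile normalization 4 each. The position trend, the row numbers as given, rows with a gene, the scaled and quantile-normalized lists and all correlations between samples but the main ones were chosen after seeing the data. Except where its construction shows it, the cause was not tested. Turning all signs left the numbers of rows and genes at 7 and 1, as it must in a 2-sided test against 0. The mean correlation between samples, 0.375, moved between 0.355 (over genes) and 0.38 (position trend removed). The depth of signal behind each value was not known. No further pairing was modelled, because each value already sets exposed against control embryos within a sample and the samples form 1 group. The test of these ratios against 0 uses that comparison within each sample. The sign of single opposing samples was not turned, since no pair correlated below 0.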

Other observations

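Some values had opposite signs in different replicates; differences between replicates were not tested. The lens and crystallin list had medians of 1.47, -0.67 and -0.41 in replicates 1, 2 and 3. Examples were cryaa (2.11, -0.63 and -1.20) and crybb1 (2.24, -0.49 and 0.05). The hatching enzymes he1.1 and he1.2, which digest the egg envelope, stood at 2.73, 4.05 and -0.15 and at 2.34, 3.83 and -0.16, while the whole hatching gland list had medians of -0.19, 0.67 and -0.15. The chaperone hsp90aa1.1 read -4.38, -3.28 and 0.38. These genes were chosen after their values were seen, and none passed in limma (adjusted p from 0.23 for he1.1 to 0.95 for cryaa).

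Further large ratios of 1 sign, chosen after their values were seen and none past the threshold, included tcap, a sarcomere protein (8.39, 1.98 and 3.63), the fast muscle troponin tnni2b.1 (4.66, 3.05 and 1.18) and the fast muscle troponin tnnt3b, which was negative (-1.77, -1.62 and -1.15). The retinaldehyde reductase dhrs3b was negative (-4.55, -1.28 and -2.54). The prolyl hydroxylase subunit p4ha1b was positive (3.18, 3.05 and 1.5), as was the endoplasmic reticulum oxidase ero1a (1.56, 2.84 and 1.37). Adjusted p in limma ran from 0.112 for p4ha1b to 0.174 for tcap, with tnni2b.1 at 0.157, tnnt3b at 0.12, dhrs3b at 0.16 and ero1a at 0.123.

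All tests of explanations were chosen after the results were seen. The row numbers and the platform's probe table did not pair as given. A candidate explanation is that the rows count the same array spots in another order. Renumbering gave r = 0.754 over 2001 pairs of probes of 1 gene, against 0.12 at most for the other numberings on the grid and 0.219 for shifts of the row numbers, and 0.663, 0.768 and 0.431 within replicates 1, 2 and 3. The 152 of these pairs with different accessions gave r = 0.514. A repeat of 266 rows in the ratios explained 2.62%, 1.1% and 3.01% of the variance in replicates 1, 2 and 3, the most among periods of 40 to 1200 rows. Anyone who names the rows by their number alone would read other genes: the largest mean ratio of the rows measured in all samples, 10.48, belongs to a cyp1a probe only after renumbering.

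The sign of the ratios is not stated. Positive values may be higher in exposed embryos: besides cyp1a, cyp1c1, which ligands of the same receptor also induce, was positive by 3.82 in its measured samples. This is a hypothesis about the table that rests on known biology and on 2 genes of 1 response. That 1 sample runs opposite to the others is argued against by the lowest correlation between samples, 0.302, and by cyp1a, which was positive in every sample. The channel that forms the numerator stays open.

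Ratios recurred between the 3 samples, and a dye effect would recur too, unless swapped hybridizations balanced it within each deposited value. A dye effect of single probes as the whole cause is argued against by pairs of probes of 1 gene with different accessions, which gave r = 0.514 over 152 pairs. These pairs rest on the renumbering, whose choice was not independent of the ratios, and probes with different accessions may still share sequence. A position trend on the array as the whole cause is argued against by the mean correlation between samples, 0.38 with the trend removed against 0.375. The design names dye swaps, and a dye effect would cancel in a value that averages both orientations. Whether each value does is not given in the sources used here, so a dye effect shared by all probes of a gene, and the exposure itself, stay open. The 3 samples have 4 sign patterns, too few for a share under 0.05, and the deposited pattern gave 7 rows, 1 gene and 314 genes of 1.5-fold, against at most 0, 0 and 58 in the others. In the patterns with 1 replicate turned, 135 to 268 rows and 90 to 163 genes had an unadjusted limma p under 0.05. For gene lists, 4 of the 4 sign patterns gave at least the 6 lists called, and the highest other gave 9.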
